A study of Arabidopsis thaliana with 36 samples.

How the data were processed

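Gene expression was measured by RNA sequencing in leaves (shoots) and roots of Arabidopsis thaliana, in the wild type (Col-0) and in the mutant opt3-2. Per the labels' protocols, seedlings spent 11 d on plates and 22 d in aerated hydroponic medium, under 16 h of light and 8 h of dark, and then 72 h in the same medium with 20 µM CdCl2. RNA of 3 to 4 plants per sample was isolated with a column kit for plants, treated with DNase, and turned into libraries with Illumina TruSeq kits, per the labels' protocols, and the labels give the molecule as poly(A) RNA. The labels give 4 groups of genotype and tissue, each with 3 biological replicates and 3 technical replicates of each. All samples had received cadmium. Untreated plants were not analysed here, so no value measures the effect of cadmium itself.

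The authors deposited a table of read counts per gene, whole numbers with no normalization, with 28775 genes and 36 columns. Per the submitters' processing notes, TopHat2 and edgeR were used with the TAIR10 genome, without versions. The counting tool, the annotation release, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Genes with near-identical copies (the PDF1.2 defensins, RBCS, LHCB1 and ribosomal RNA) are therefore uncertain as single genes, as are overlapping and antisense genes. Gene names came from a RefSeq table of the TAIR10.1 assembly, matched on the locus code: 28009 of the 28775 codes matched, and the 766 that did not held 0.154% of all counts and were kept under their code. Mitochondrial and chloroplast codes were not paired with names by that table.

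The technical replicates of a library differed by little more than sampling noise: among genes with at least 30 counts, their variance was 1.02 to 1.06 times the Poisson value, against 12.2 to 29.5 times between biological replicates. The first ratio used counts of single technical replicates and the second counts summed over 3. Such a ratio grows with depth when replicates vary beyond sampling noise, so the sizes are not directly comparable. They were summed, which gave 12 libraries and n = 3 per group. Replicates are plant samples that the labels call biological; whether they were grown in separate batches is not stated. The columns carry run suffixes whose meaning is not stated. All opt3-2 libraries have suffixes 1 to 3, and wild type libraries have 2 to 4 or 5 to 7, so suffix and genotype overlap only in part.

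Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group left 21887 genes, TMM factors scaled the libraries, and a group-means model over the 12 libraries, with 8 residual degrees of freedom, was tested by the robust quasi-likelihood F test. The square root of the common dispersion was 0.115. Calls rest on a Benjamini-Hochberg adjusted p below 0.05, two-sided; an adjusted p given for a gene comes from this test. Standard errors of log2 fold changes were taken as the fold change over the square root of F. CPM (counts scaled to a common library size) were computed from the deposited counts with TMM-scaled library sizes, and are given as mean ± SD of 3 libraries. A count of 3 stands as the floor for a group at 0; floors cover counting error only. The comparisons are opt3-2 against wild type in shoots and in roots, the difference between those differences (the interaction), and roots against shoots in each genotype. Overlap between the shoot and root calls was tested with Fisher's exact test per direction; these comparisons share no libraries.

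A set of 28 gene lists (391 entries, of which 382 were measured) was fixed by locus code. It covers iron uptake, iron-deficiency regulators, iron storage, copper, zinc, cadmium detoxification, sulfur, oxidative stress, heat shock, salicylic acid defence, jasmonate, ethylene, abscisic acid, photosynthesis, tetrapyrroles, senescence, the clock, phosphate, nitrate, suberin and Casparian strip, glucosinolates, flavonoids, the cell cycle, and markers of phloem, xylem, guard cells, root hairs and root tissue. ATPS1 and ATPS3, entries whose symbol the reference gives to another locus, were dropped (2 in all), and 29 entries carry a symbol that the reference does not list. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry stand beside it. Genes were named by a rule: OPT3; in each tissue the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in a group and groups that do not overlap (which chance gives for 10% of genes); the 4 members of each iron list with the smallest p; 2 members of each other list that was called or had 25% or more of its members called; for the interaction, the 5 smallest p and up to 8 iron genes; and RBCS1A, PYK10 and CASP1 between tissues. The text gives a part of the genes this rule names. FRO2, FIT, MYB72, NAS2, HMA3, IMA1, IMA2, IMA3, BHLH38, BHLH39, BHLH100, BHLH101, PYE, NRT1.8, SAG13, HSP101 and JAZ10, VTL2 in shoots, and AHA2, FER3, FER4 and IRT1 in roots were chosen after their values were seen, as were the mitochondrial and ribosomal RNA genes.

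The design, the lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were other scalings (RLE, upper quartile, library sizes alone), DESeq2 1.42.0, limma-voom, no or a stricter low-count filter, a single technical replicate, only the 6 libraries compared, a replicate block, shared run suffixes only, a term for the wild type suffixes, stricter thresholds, and each replicate left out. DESeq2 was run without gene lists, and the 6-library setting without the interaction. The procedure was tested on simulated data: negative binomial counts for 21649 genes from the wild type means, the library sizes and the dispersions, with genes changed 1.5-fold, 2-fold or 4-fold in each tissue and 1 list per tissue raised 2-fold, which was called. In shoots 74.6%, 95.5% and 95.5% of the changed genes were recovered at these sizes; in roots 71.6%, 92.5% and 100%; for the interaction 37.3%, 82.1% and 95.5%. False calls made up 7.04% of calls in shoots, 4.10% in roots and 2.61% for the interaction, and 0 of 27 unchanged lists were called. The genes were simulated independently, so list calls with correlated members were not tested (estimated correlation 0.777 for photosynthesis in shoots). Few genes were changed, whereas 43.9% were called in the data in shoots and 39.0% in roots. The simulated shares of false calls need not hold there. A test of 231 annotation terms was added after the values were seen. Plots were drawn with matplotlib 3.10.9.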

Results

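The 36 samples were leaves (shoots) and roots of wild type (Col-0) and opt3-2 plants, all after 72 h in 20 µM CdCl2. The gene OPT3, mutated in opt3-2, encodes a transporter that moves iron into the phloem, and the series title places the plants in a study of how cadmium interferes with iron sensing. Summed over technical replicates, they form 12 libraries, 3 in each of 4 groups. Total counts ran from 27229534 to 33221855 in wild type shoots and from 21262406 to 29692680 in opt3-2 shoots. In roots they ran from 35523985 to 36484138 in wild type and from 22449113 to 25141843 in opt3-2. At these depths 1 library's floor of 3 counts lies between 0.0705 and 0.167 CPM. The first principal component of log2 CPM, with 91.8% of the variance, separated shoots from roots, and the next, with 3.48%, separated the genotypes within each tissue in opposite directions. On it, wild type shoot replicate 2 (-25.0) lay nearer the other genotype than replicates 1 (-52.3) and 3 (-47.9), and opt3-2 shoot replicate 3 (28.7) nearer than replicates 1 (44.9) and 2 (44.4). The third component, with 2.115%, separated the genotypes in the same direction in both tissues. All opt3-2 libraries lay at 18.3 or above on that component and all wild type libraries at -19.5 or below.

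OPT3 (AT4G16370; chromosome 4, 9247302 to 9250343 on the minus strand of TAIR10.1) was lower in every opt3-2 library than in every wild type library of the same tissue. Wild type shoots held 389, 321, 352 CPM in replicates 1, 2 and 3, and opt3-2 shoots 23.4, 17.59, 24.1 CPM. Wild type roots held 38.4, 47.9, 41.4 CPM and opt3-2 roots 9.02, 4.55, 4.13 CPM. OPT3 transcript fell by 16.3-fold in shoots (log2 -4.02 ± 0.25, SE, n = 3 per group; adjusted p = 1.92e-06) and by 7.27-fold in roots (log2 -2.86 ± 0.25; adjusted p = 1.48e-05).

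**Figure D1:**
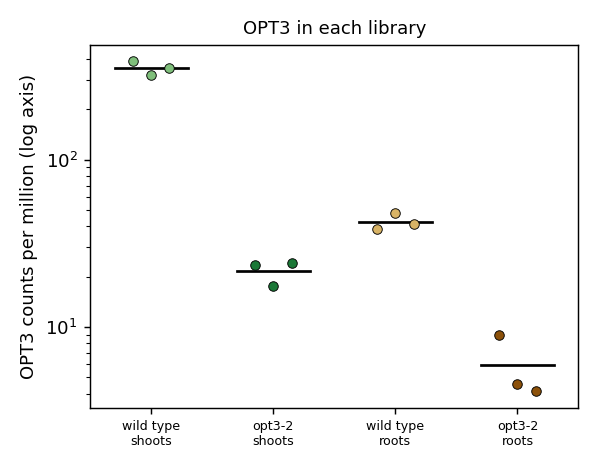
OPT3 transcript in CPM on a log axis, for each of the 12 libraries (points) with the group mean (line). In both tissues the 3 opt3-2 libraries lie below the 3 wild type libraries.

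In shoots the question was what the mutation changes in leaves under cadmium. Of 12 genes of iron storage and iron sufficiency 10 rose in opt3-2, while 11 of 18 jasmonate genes and 9 of 18 salicylic acid genes fell and 1 of the latter rose. The jasmonate and salicylic acid lists were not called with an estimated correlation (adjusted p = 0.382 and adjusted p = 0.341 with an estimated correlation). NAS3, a nicotianamine synthase, had 11.7 ± 5.10 CPM in wild type and 238 ± 45.5 CPM in opt3-2 (n = 3 each). NEET, an iron-sulfur cluster protein, had 2.58 ± 1.14 CPM in wild type and 39.9 ± 2.16 CPM in opt3-2. The ferritin FER4, an iron store of plastids and mitochondria, had 9.29 ± 1.02 CPM in wild type and 41.5 ± 0.980 CPM in opt3-2. PR5, a pathogenesis-related protein of the salicylic acid response, stood at 2292 ± 132 CPM in wild type and 79.9 ± 22.0 CPM in opt3-2. Of 21887 genes tested, 4660 were higher and 4957 lower in opt3-2 shoots, and 521 and 1193 of these changed 2-fold or more.

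Counts adjusted over the list alone are given where they differ; for all other lists named in shoots they were the same. Of 12 measured genes of the iron storage list, 10 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone; median log2 1.59, camera adjusted p = 2.22e-15, and adjusted p = 0.0274 with an estimated correlation). They include the ferritins FER3 (log2 1.97 ± 0.12, SE) and FER4 (2.16 ± 0.12), the metal-nicotianamine transporter YSL1 (1.46 ± 0.09) and the vacuolar iron transporter-like gene VTL2 (2.24 ± 0.20). Among 23 iron-deficiency regulators 5 rose and 9 fell, and the list as a whole did not pass (adjusted p = 0.398; adjusted p = 0.837 with an estimated correlation). ZIF1, a vacuolar carrier for nicotianamine, fell from 163 to 68.7 CPM (log2 -1.24 ± 0.12), and BTS, a ubiquitin ligase that restrains the iron-deficiency response, from 448 to 262 CPM (-0.77 ± 0.12). PYE (-0.55 ± 0.14), a repressor within that response, and the small peptide gene IMA3 (-0.77 ± 0.17) also fell, whereas BHLH38 (0.60 ± 0.20), BHLH39 (0.57 ± 0.18) and NAS4 (1.05 ± 0.18) rose. Of 21 iron uptake genes 6 rose and 0 fell, among them IRT1, the main ferrous iron transporter, from 0.760 to 2.11 CPM (log2 1.47 ± 0.28). That list passed with adjusted p = 0.0279, but adjusted p = 0.382 with an estimated correlation and 0.0505 without wild type shoot replicate 2.

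**Figure D2:**
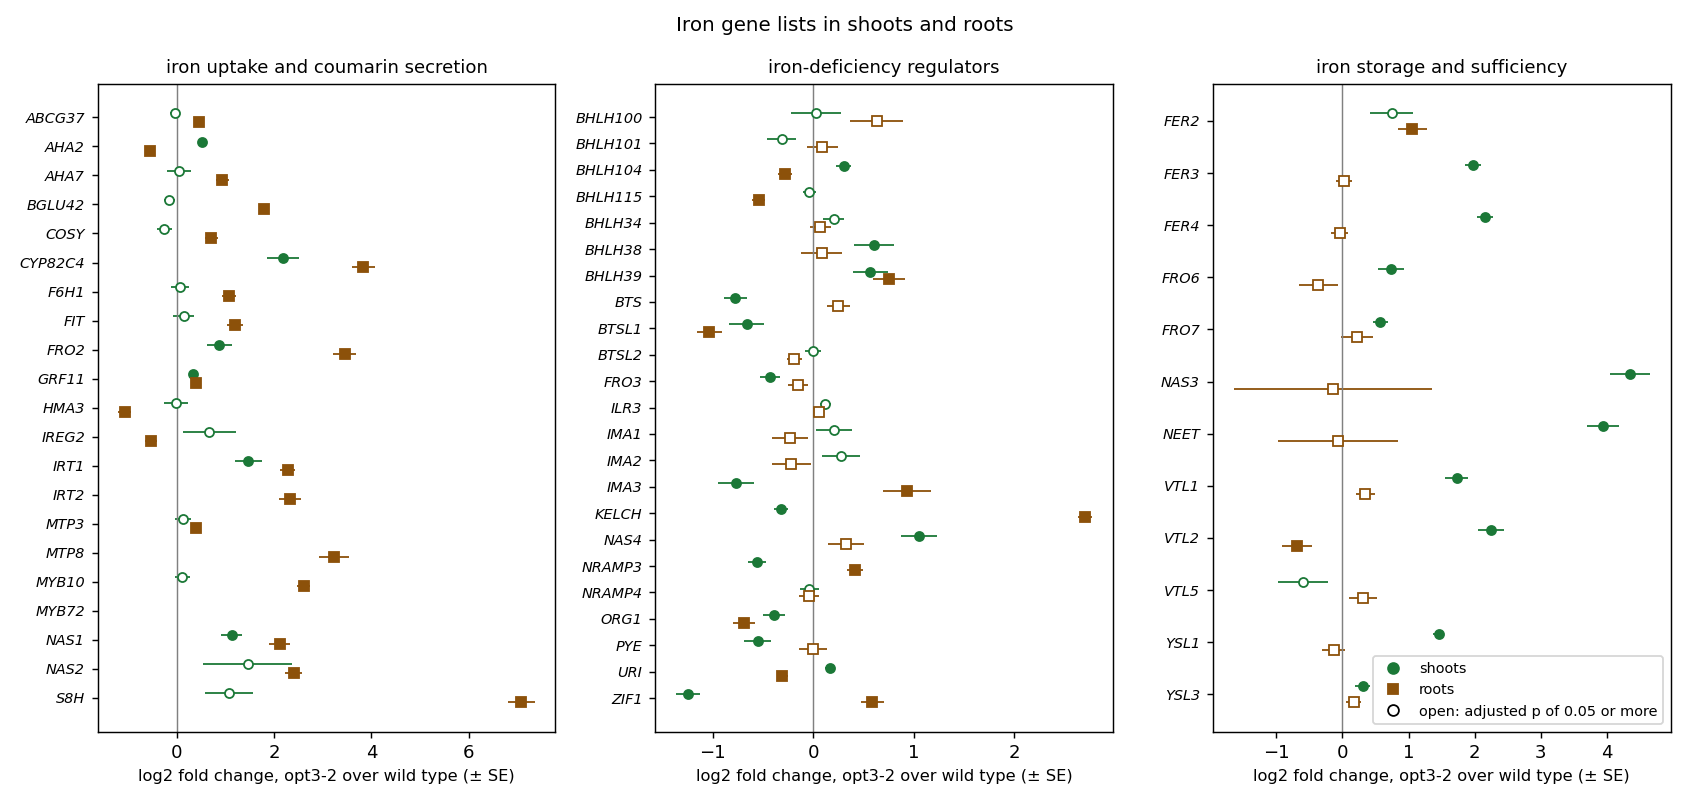
Log2 fold change of opt3-2 over wild type with its SE (n = 3 libraries per group) for the members of 3 iron gene lists, in shoots (circles) and roots (squares). Filled symbols have an adjusted p below 0.05, members with 3 or fewer counts in a group of that tissue are not drawn, and most storage genes lie right of 0 in shoots while most uptake genes lie right of 0 in roots.

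For sulfur, 12 of 17 genes rose and 1 fell (median 0.56, adjusted p = 1.08e-04; adjusted p = 0.227 with an estimated correlation). LSU1, a marker of sulfur limitation, stood at log2 3.66 ± 0.37 and APR1, a reductase of sulfate assimilation, at 1.16 ± 0.12. Glucosinolate synthesis had 12 of 15 genes higher and 2 lower (median 0.76, adjusted p = 2.88e-11, adjusted p = 0.0472 with an estimated correlation). MAM1, which extends methionine side chains, went from 121 to 521 CPM (2.11 ± 0.11). For copper, 4 of 15 genes rose and 0 fell, among them the iron superoxide dismutase FSD1 (1.16 ± 0.09) and the chaperone CCH (0.45 ± 0.08). The list passed at adjusted p = 0.0363, against adjusted p = 0.277 with an estimated correlation and 0.0531 without wild type shoot replicate 3. In the phosphate list 8 of 14 genes rose and 1 fell (adjusted p = 0.0112; adjusted p = 0.153 with an estimated correlation). One that rose is the acid phosphatase PAP17 (0.90 ± 0.10). The zinc list, with 3 higher and 3 lower of 13, did not pass (adjusted p = 0.376). The zinc transporters ZIP4 (-1.11 ± 0.09) and IRT3 (-1.20 ± 0.10) fell. Neither did cadmium detoxification, with 4 higher and 3 lower of 15 (adjusted p = 0.633), in which GSH1, the first enzyme of glutathione synthesis, fell (-0.44 ± 0.08). The nitrate list had 2 higher and 1 lower of 7 (adjusted p = 0.268). The nitrite reductase NIR1 stood at 0.92 ± 0.06 and the transporter NRT1.8 at -3.26 ± 0.51; the list's median (0.04) and mean (-0.24) differ in sign.

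Among hormone and stress lists in shoots, jasmonate genes fell most: 11 of 18 were lower and 0 higher (13 and 0 adjusted over the list alone; median -1.97, adjusted p = 8.90e-05; adjusted p = 0.382 with an estimated correlation). The defensin gene PDF1.2A fell from 1649 to 6.23 CPM (log2 -8.05 ± 0.83), JAZ10, a repressor induced by the hormone, by 4.47 on the log2 scale, and TAT3, a tyrosine aminotransferase, from 135 to 10.3 CPM (-3.71 ± 0.32). The largest falls of all named by rule were PDF1.2A and its near-identical relatives PDF1.2b (-8.82 ± 0.81), PDF1.2c (-8.61 ± 0.83) and PDF1.3 (-8.57 ± 0.96), whose reads cannot be assigned to single copies with certainty. Wild type shoot replicate 2 held less of these transcripts than the other replicates: PDF1.2A was at 2426, 349.7, 2170.3 CPM in replicates 1, 2 and 3, and without replicate 2 the jasmonate list had 15 lower and 0 higher. In the salicylic acid list 9 of 18 genes fell and 1 rose (median -0.45, adjusted p = 0.00166; adjusted p = 0.341 with an estimated correlation). PR5 stood at -4.84 ± 0.21 and PR2, a glucanase, at -3.83 ± 0.23. In the heat shock list 7 of 17 fell and 1 rose, with the luminal chaperone gene BIP3 at -3.71 ± 0.17 (adjusted p = 0.00556; adjusted p = 0.341 with an estimated correlation and 0.0503 without wild type shoot replicate 2). Abscisic acid genes rose in 8 of 12 cases and fell in 0 (adjusted p = 0.00128; adjusted p = 0.233 with an estimated correlation). They include the phosphatase ABI1 (0.89 ± 0.07). Ethylene genes, 2 higher and 5 lower of 11 (adjusted p = 0.268), and oxidative stress genes, 4 higher and 7 lower of 29 (adjusted p = 0.761), did not pass as lists. The catalase gene CAT1 rose from 32.3 to 125 CPM (1.96 ± 0.11).

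Photosynthesis genes rose in 15 of 26 cases and fell in 0 (median 0.39, adjusted p = 0.00164; adjusted p = 0.600 with an estimated correlation). The ferredoxin gene FD2 went from 464 to 939.7 CPM (1.02 ± 0.12). Tetrapyrrole synthesis had 5 of 10 genes higher and 1 lower, with HEMA1 at 0.87 ± 0.16 (adjusted p = 0.116; 0.0388 without opt3-2 shoot replicate 1). Senescence genes rose in 7 of 12 cases and fell in 1 (adjusted p = 0.00588; adjusted p = 0.341 with an estimated correlation). NYC1, which degrades chlorophyll b, rose (1.67 ± 0.13) and SAG13 fell (-1.22 ± 0.28). In the cell cycle list 7 of 8 genes fell and 0 rose (median -1.19, adjusted p = 1.31e-05; adjusted p = 0.233 with an estimated correlation). The replication genes PCNA1 (-2.42 ± 0.19) and MCM2 (-2.17 ± 0.25) fell. The clock list had 5 higher and 2 lower of 12 (6 and 2 adjusted over the list alone; adjusted p = 0.0335; adjusted p = 0.341 with an estimated correlation, and 0.0586 without opt3-2 shoot replicate 1). GI stood at 0.90 ± 0.09. Suberin and Casparian strip genes fell in 6 of 14 cases and rose in 0, with the reductase FAR1 at -1.08 ± 0.09 (adjusted p = 0.0279; adjusted p = 0.382 with an estimated correlation, and 0.0591 without opt3-2 shoot replicate 3). The flavonoid list had 0 higher and 2 lower of 10 (adjusted p = 0.946), with a median of 0.07 and a mean of -0.12.

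Phloem markers rose in 4 of 7 cases and fell in 0, with AHA3 at 0.60 ± 0.08 (adjusted p = 0.0279; adjusted p = 0.341 with an estimated correlation, and 0.0525 without wild type shoot replicate 3). Guard cell markers rose in 3 of 5 cases, with the anion channel gene SLAC1 at 1.14 ± 0.12 (adjusted p = 0.0329; adjusted p = 0.317 with an estimated correlation, and 0.0663 without opt3-2 shoot replicate 3). Xylem markers had 1 higher and 2 lower of 8 (1 more higher adjusted over the list alone; adjusted p = 0.761). The peptidase gene XCP1 stood at -1.03 ± 0.14; the markers' median was 0.08 and their mean -0.05. None of 6 root hair markers passed in edgeR (list adjusted p = 0.913). Of these, RHD6, RSL4, EXPA18 and EXPA7 had 3 or fewer counts over each group of shoot libraries, too few to show a difference. Abundant root transcripts had 0 higher and 1 lower of 7 (adjusted p = 0.633). limma-voom called 10 of the 28 lists in shoots against 17, and iron uptake, copper, heat shock, salicylic acid, senescence, clock and suberin were not among them. Other alternatives also ended calls near the threshold in shoots: single technical replicates for iron uptake, copper, the clock, suberin and guard cells, the shared run suffixes or the 6 shoot libraries alone for copper and the clock, and fry for photosynthesis. With library sizes alone as scaling, 3259 genes were higher and 5941 lower in opt3-2 shoots, 35.4% higher against 48.5% with TMM factors. RLE factors gave 5423 higher and 4461 lower (54.9% higher) and DESeq2 5474 and 4529 (54.7%), so which direction holds more genes depends on the scaling.

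In roots the question was the same, and here 18 of 21 genes of iron acquisition, 15 of 17 heat shock genes and 10 of 12 abscisic acid genes rose, lists that also passed with an estimated correlation. Of 18 salicylic acid genes 12 rose, a list that did not pass so (adjusted p = 0.0558 with an estimated correlation). S8H, an enzyme of the secreted coumarin fraxetin, had 1.35 ± 0.248 CPM in wild type and 183 ± 51.0 CPM in opt3-2, 135-fold higher (n = 3 each). The ferric reductase FRO2 had 26.7 ± 7.29 CPM in wild type and 292 ± 68.9 CPM in opt3-2. IRT1 had 88.9 ± 10.03 CPM in wild type and 432 ± 71.5 CPM in opt3-2. HSP17.6II, a cytosolic small heat shock protein, had 3.74 ± 0.812 CPM in wild type and 187 ± 29.4 CPM in opt3-2. Of 21887 genes 3828 were higher and 4702 lower in opt3-2 roots, and 1151 and 576 of these changed 2-fold or more.

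For lists in roots, too, counts adjusted over the list alone were the same unless given. Of 21 iron uptake genes 18 rose and 3 fell (median log2 1.797, adjusted p = 2.66e-22, and adjusted p = 0.0106 with an estimated correlation). Besides S8H (7.08 ± 0.27, SE), FRO2 (3.45 ± 0.23) and IRT1 (2.28 ± 0.15), the transcription factor genes MYB10 (2.61 ± 0.12) and FIT (1.19 ± 0.16) and the nicotianamine synthase NAS2 (2.40 ± 0.18) rose. MYB72, a partner of MYB10, had no count in any wild type root library and 2.45 CPM over the opt3-2 root libraries, at least 101-fold above the floor of 3 counts over the wild type group. With it at that bound the list's median stayed 1.797. The proton pump AHA2 (-0.55 ± 0.08) and HMA3 (-1.06 ± 0.13) fell. Among 23 iron-deficiency regulators 5 rose and 5 fell (adjusted p = 0.302): the KELCH gene AT3G07720 rose from 45.1 to 294 CPM (2.70 ± 0.07), IMA3 (0.93 ± 0.24) and BHLH39 (0.75 ± 0.16) rose, and BTSL1, a ubiquitin ligase gene, fell (-1.03 ± 0.12). IMA1 (-0.23 ± 0.18), IMA2 (-0.22 ± 0.19), BHLH100 (0.63 ± 0.27) and BHLH101 (0.09 ± 0.16), which respond to iron shortage, did not pass. The iron storage list had 1 higher and 1 lower of 12 (1 and 0 adjusted over the list alone; adjusted p = 0.778). FER3 stood at 0.02 ± 0.12 and FER4 at -0.04 ± 0.13; the list's median (-0.01) and mean (0.06) differ in sign.

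Sulfur genes rose in 11 of 17 cases and fell in 3 (adjusted p = 5.23e-07; adjusted p = 0.0567 with an estimated correlation). BGLU28, a glucosidase induced by sulfur limitation, rose from 0.299 to 20.0 CPM (6.05 ± 0.23) and the sulfate transporter SULTR2;1 from 13.4 to 93.4 CPM (2.80 ± 0.11). Zinc genes fell in 6 of 13 cases and rose in 1 (adjusted p = 0.0255; adjusted p = 0.104 with an estimated correlation). Among those that fell were HMA2, a pump that exports zinc and cadmium toward the xylem (-1.72 ± 0.16), and ZIP4 (-0.91 ± 0.09). Nitrate genes fell in 4 of 7 cases and rose in 0 (adjusted p = 0.00163; adjusted p = 0.0570 with an estimated correlation). Among these were the nitrate reductase NIA1 (-1.17 ± 0.11) and the transporter NRT1.1 (-1.49 ± 0.15). Cadmium detoxification had 5 higher and 2 lower of 15 (adjusted p = 0.402). The phytochelatin synthase PCS2 stood at 1.06 ± 0.18 and the vacuolar transporter ABCC2 at 0.39 ± 0.07. Copper genes, 4 higher and 3 lower of 15 (adjusted p = 0.933), and phosphate genes, 7 higher and 3 lower of 14 (adjusted p = 0.323), did not pass as lists. The copper list's median (-0.01) and mean (-0.05) lay below 0 while its test pointed up. Among the largest falls was SKOR, a potassium channel that releases potassium into the xylem, from 45.2 to 4.88 CPM (-3.22 ± 0.16).

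Of 17 heat shock genes 15 rose and 0 fell in roots (median 2.56, adjusted p = 1.45e-48, and adjusted p = 0.00411 with an estimated correlation). HSP17.6II stood at 5.64 ± 0.17, the coactivator MBF1C at 2.47 ± 0.07 and the disaggregase HSP101 at 1.77 ± 0.10. Abscisic acid genes rose in 10 of 12 cases and fell in 0 (median 2.17, adjusted p = 9.97e-09, and adjusted p = 0.0418 with an estimated correlation). They include the phosphatase HAI1 (2.50 ± 0.19) and KIN2 (2.21 ± 0.19). In the salicylic acid list 12 of 18 rose and 0 fell (adjusted p = 1.89e-11; adjusted p = 0.0558 with an estimated correlation). CYP71A13, of camalexin synthesis, stood at 3.50 ± 0.22 and ICS1, of salicylic acid synthesis, at 0.91 ± 0.07. Oxidative stress genes rose in 13 of 29 cases and fell in 1 (14 and 1 adjusted over the list alone; median 0.70, adjusted p = 2.53e-08; adjusted p = 0.173 with an estimated correlation). Those that rose include the alternative oxidase AOX1A (1.22 ± 0.08) and the mitochondrial dehydrogenase NDB2 (1.15 ± 0.08). Jasmonate genes rose in 7 of 18 cases and fell in 0, with TAT3 at 2.68 ± 0.35 (adjusted p = 0.00320; adjusted p = 0.682 with an estimated correlation). Senescence genes rose in 5 of 12 cases and fell in 1, with the transcription factor gene NAP at 0.99 ± 0.13 (adjusted p = 0.01001; adjusted p = 0.324 with an estimated correlation). Cell cycle genes rose in 8 of 8 cases, with CDKB1;1 at 0.84 ± 0.14 (adjusted p = 9.70e-04; adjusted p = 0.317 with an estimated correlation). Ethylene, with 5 higher and 3 lower of 11 (adjusted p = 0.577), and the clock, with 2 higher and 6 lower of 12 (adjusted p = 0.264), did not pass as lists. EBF2, which degrades ethylene's transcription factors, fell (-0.69 ± 0.09), as did PRR7 (-0.64 ± 0.07).

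**Figure D3:**
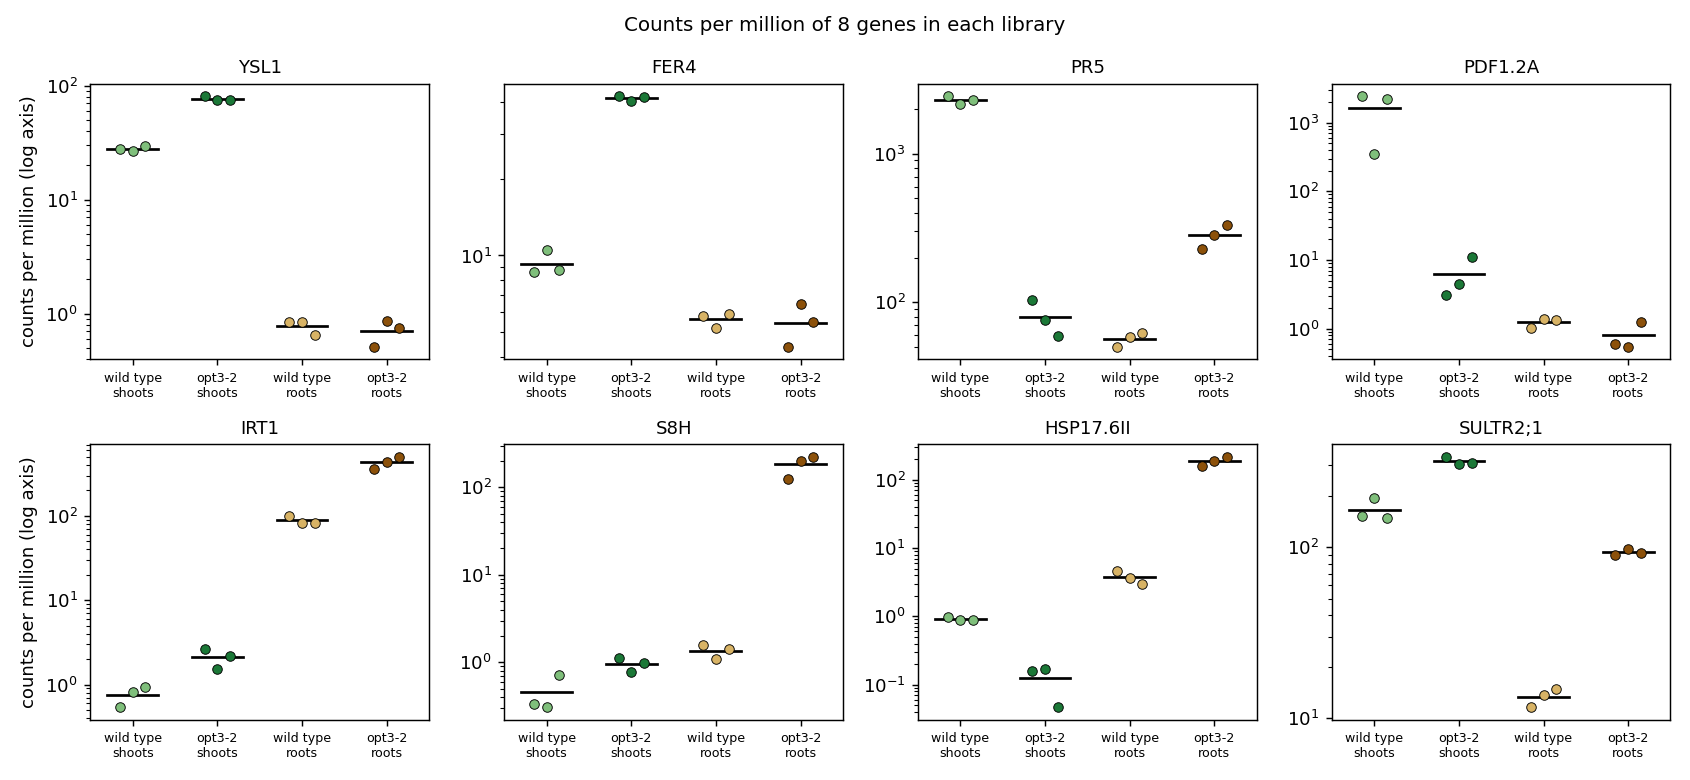
CPM on a log axis (a scale of its own for each gene) of 8 genes in each of the 12 libraries, with the mean of each group of 3 as a line. YSL1 and FER4 are highest in opt3-2 shoots, PR5 and PDF1.2A in wild type shoots, and IRT1, S8H and HSP17.6II in opt3-2 roots.

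Flavonoid genes rose in 3 of 10 cases and fell in 0 in roots (adjusted p = 0.0643; 0.0396 without wild type root replicate 1 and 0.0402 without opt3-2 root replicate 3). PAL1, the entry to phenylpropanoids, stood at 1.02 ± 0.14. Photosynthesis genes, leaf markers in a root sample, rose in 3 of 26 cases and fell in 1 (1 and 0 adjusted over the list alone; adjusted p = 0.141; 1.25e-04 without wild type root replicate 3). Tetrapyrrole synthesis had 3 higher and 1 lower of 10 (adjusted p = 0.843), glucosinolates 6 higher and 3 lower of 15 (7 and 4 adjusted over the list alone; adjusted p = 0.755), and suberin genes 0 higher and 3 lower of 14 (adjusted p = 0.577). In these lists CHLM (-0.92 ± 0.09) and MYB28, an activator of aliphatic glucosinolates (-1.38 ± 0.10), fell. Root hair markers rose in 3 of 6 cases and fell in 0 (adjusted p = 0.2004; 0.00442 without wild type root replicate 1). The expansin EXPA18 stood at 0.84 ± 0.19. Phloem markers had 1 higher and 1 lower of 7 (adjusted p = 0.898), xylem markers 2 and 1 of 8 (adjusted p = 0.406), guard cell markers 1 and 0 of 5 (adjusted p = 0.482) and abundant root transcripts 0 and 3 of 7 (adjusted p = 0.258), PYK10, a root glucosidase, among the latter (-0.55 ± 0.08). Restricted to the run suffixes that both genotypes share, roots had 1684 genes higher and 2119 lower, with 1 wild type library left that is assumed to vary like the other groups. The zinc (adjusted p = 0.120), jasmonate (0.161) and senescence (0.222) lists were then not called. Which direction held more genes in roots also depended on the scaling, with 4246 higher and 4178 lower by RLE factors, 4215 and 4086 by upper-quartile factors and 4416 and 4225 by DESeq2. The stricter low-count filter also ended the call of the zinc list.

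**Figure D4:**
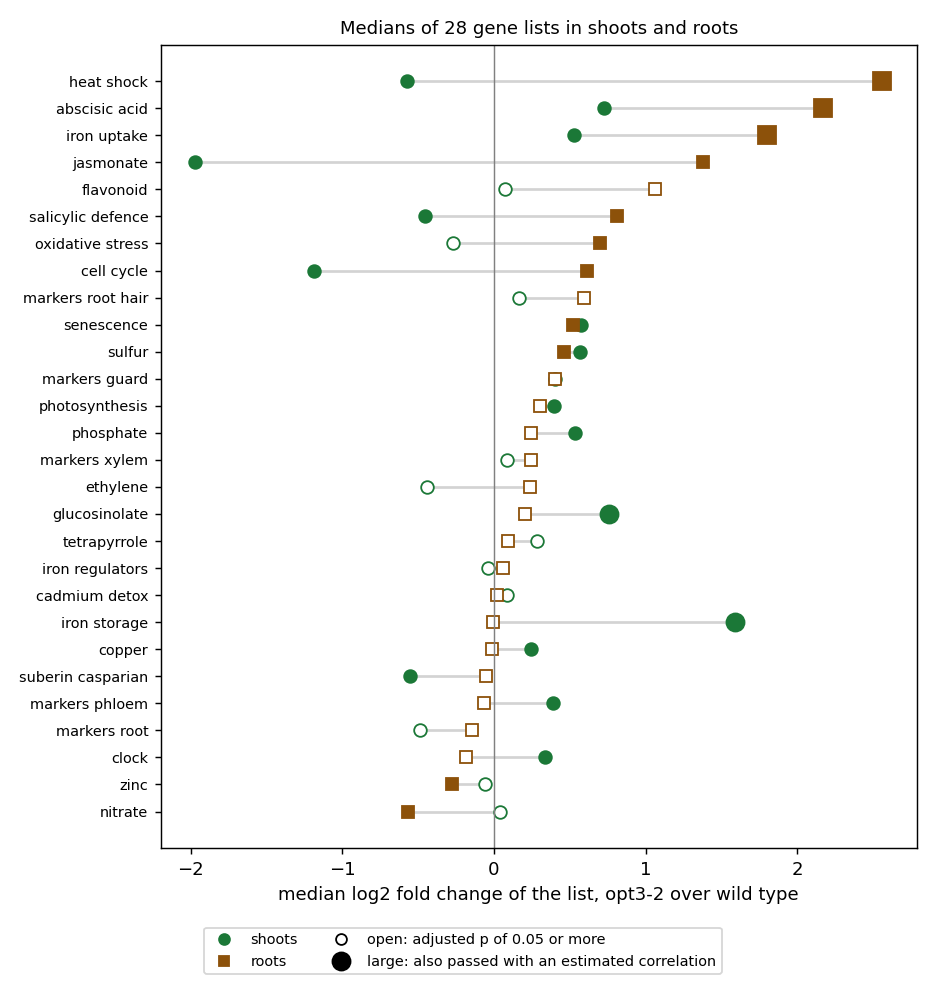
Median log2 fold change of opt3-2 over wild type for the 28 gene lists in shoots (circles) and roots (squares). Filled symbols passed camera at an adjusted p below 0.05, larger ones also with an estimated correlation, and the heat shock, jasmonate, salicylic acid and cell cycle lists lie left of 0 in shoots and right of 0 in roots.

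The comparison of shoots with roots asked whether the genotype difference depends on the tissue, and many genes moved in opposite directions. AT5G52390, of the PAR1 protein family, fell in shoots, from 43.2 to 4.83 CPM, and rose in roots, from 46.4 to 227 CPM, a difference of log2 -5.45 ± 0.16 (SE, n = 3 per group; adjusted p = 7.90e-09). FER4 rose in shoots and did not pass in roots, where it went from 5.61 to 5.44 CPM, and the difference itself passed (log2 2.197 ± 0.17), as for FER3 (1.95 ± 0.17). KELCH (-3.02 ± 0.09), MYB10 (-2.49 ± 0.20) and BGLU42 (-1.95 ± 0.15), genes of the root iron response, had the more positive effect in roots, and ZIF1 fell in shoots and rose in roots (-1.83 ± 0.17). For AHA2, higher in shoots and lower in roots, the difference was 1.08 ± 0.11. The difference passed for 10542 genes, 5249 with the more positive effect in shoots and 5293 in roots. That balance depended on the scaling. Library sizes alone gave 4328 and 5926 and upper-quartile factors 4763 and 5591, whereas RLE factors gave 5446 and 5160 and DESeq2 5458 and 5252.

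Other genes with the smallest p of the difference were AT1G55210, a dirigent-like gene (-3.61 ± 0.14), the transcription factor gene WRKY71 (3.00 ± 0.12) and AT1G54050, a small chaperone gene (-5.23 ± 0.21). VTL2 rose in shoots and was lower in roots (2.92 ± 0.30). Its root value of -0.68 ± 0.23 was not called in 8 of 20 alternatives, with adjusted p up to 0.214. Among these it lost its call without opt3-2 root replicate 1 (adjusted p = 0.0738), wild type root replicate 1 (0.0689) or wild type root replicate 2 (0.104). Of 116 genes named by rule for shoots or roots, 91 passed the test of the difference, and 56 of these had fold changes of opposite sign. Signs were counted whether or not each value was called. The 56 thus include FER4, not called in roots, and NEET, which lay near the floor there (0.0885 and 0.0841 CPM). A sign alone does not show that a gene moved in both tissues. Across genes, which are not independent replicates, the log2 fold changes in shoots and roots had a Spearman correlation of -0.26. Genes called lower in shoots and higher in roots numbered 1442 against 867 by chance (Fisher's exact test, odds ratio 2.50, p = 1.55e-120). Those higher in shoots and lower in roots numbered 1764 against 1001 (same exact test, odds ratio 2.96, p = 5.91e-188). Genes higher in both numbered 604 against 815 by chance (Fisher's exact test, odds ratio 0.647, p = 4.94e-21) and lower in both 457 against 1065 (same exact test, odds ratio 0.303, p = 7.85e-145). These exact tests treat genes as independent, which they are not, so their p does not measure variation between replicates. Both sets of calls also use a spread estimated over all 12 libraries, so the chance numbers are approximate. Among changes of 2-fold or more, 87 genes were higher in both against 27.4 by chance and 18 lower in both against 31.4. At that size 41 were higher in shoots and lower in roots against 13.7, and 187 the other way against 62.7.

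Counts adjusted over the list alone were the same for the lists named here unless given. Heat shock genes had a more positive effect in roots in 14 of 17 cases (adjusted p = 5.25e-20; adjusted p = 0.0595 with an estimated correlation). Jasmonate genes had it in 15 of 18 (adjusted p = 1.71e-06; adjusted p = 0.463 with an estimated correlation) and cell cycle genes in 8 of 8 (adjusted p = 3.13e-07; adjusted p = 0.1504 with an estimated correlation). Iron uptake genes had it in 11 of 21 cases against 2 with the more positive effect in shoots (12 and 2 adjusted over the list alone; adjusted p = 0.00884; adjusted p = 0.463 with an estimated correlation). Salicylic acid genes (11 against 1 of 18; adjusted p = 1.77e-10; adjusted p = 0.121 with an estimated correlation) and oxidative stress genes (15 against 2 of 29; adjusted p = 0.00111; adjusted p = 0.568 with an estimated correlation) lay the same way. Iron storage genes had the more positive effect in shoots in 8 of 12 cases and in roots in 0 (adjusted p = 1.15e-04; adjusted p = 0.1504 with an estimated correlation). Glucosinolate genes had it in 6 of 15 and 1 (adjusted p = 5.70e-04; adjusted p = 0.233 with an estimated correlation), and clock genes in 6 of 12 and 1 (adjusted p = 0.0194; adjusted p = 0.431 with an estimated correlation). Single alternatives ended 3 of these calls: iron uptake with technical replicate 1 alone (adjusted p = 0.0515), oxidative stress with the shared run suffixes (0.0567) and the clock with limma-voom (0.0612). Nitrate genes had it in 5 of 7 cases and 1 (adjusted p = 0.00844; adjusted p = 0.1504 with an estimated correlation, and 0.152 without wild type shoot replicate 2). The abscisic acid list did not pass (adjusted p = 0.107), but it did without opt3-2 root replicate 2 (0.0257) or wild type root replicate 3 (0.0283). With an estimated correlation 0 lists passed for the difference, while 6 had an unadjusted p below 0.05 and fry called 19. With the shared run suffixes only, 3298 genes had the more positive effect in shoots and 3409 in roots.

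**Figure D5:**
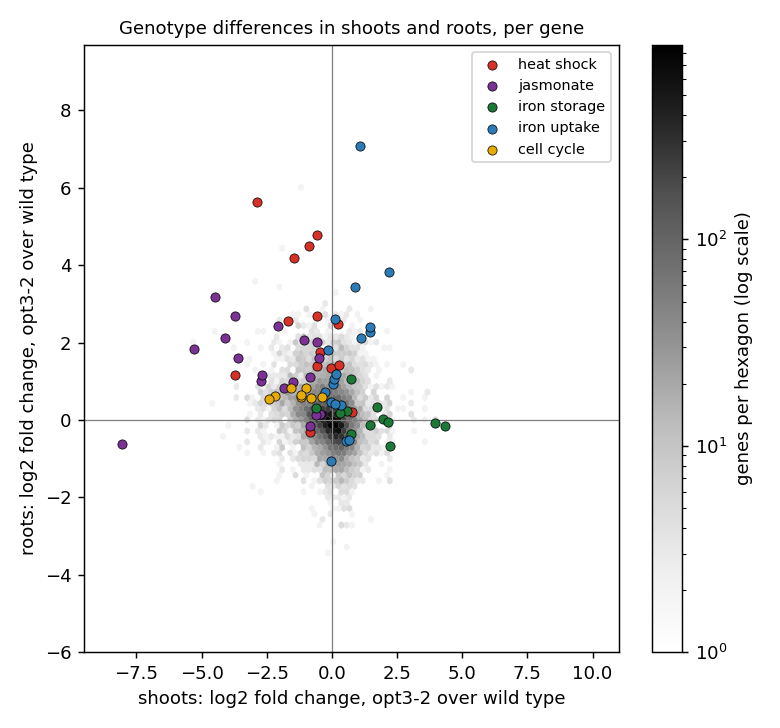
Log2 fold change of opt3-2 over wild type in shoots (horizontal) and roots (vertical) for 21887 genes, as a density in grey, with the members of 5 gene lists as points (members with 3 or fewer counts in a group are left out). Most heat shock and jasmonate genes lie to the upper left, most iron storage genes to the right and most iron uptake genes upward.

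Between tissues, RBCS1A, the small subunit of the carbon-fixing enzyme, stood in roots at log2 -8.12 ± 0.23 in wild type and -7.80 ± 0.23 in opt3-2 (root minus shoot; n = 3 per group). PYK10 was higher in roots by 5.31 ± 0.10 and 5.16 ± 0.10, and CASP1, of the Casparian strip, by 7.46 ± 0.33 and 7.80 ± 0.37. CASP1 held 0.139 ± 0.0963 CPM in wild type shoots and 0.0889 ± 0.0311 CPM in opt3-2 shoots, near or under the floor of 3 counts per library, and over the alternatives its log2 value ran from 6.93 to 8.19 in wild type and from 6.40 to 10.87 in opt3-2. All 26 photosynthesis genes were lower and all 7 root markers higher in roots of both genotypes. Iron uptake genes were higher in roots in 17 of 21 cases in wild type and 20 in opt3-2, and lower in 1 in each. In wild type roots 8636 genes were higher and 8444 lower than in shoots, and in opt3-2 9540 and 8973. Camera called 17 of 28 lists in wild type and 18 in opt3-2. With an estimated correlation it called 0 in each, with 9 and 8 at an unadjusted p below 0.05, while fry called 27 and 25. With library sizes alone the medians of all genes shifted by 0.35 and 0.43 on the log2 scale and the higher and lower counts became 12232 and 5876 in wild type and 12450 and 6196 in opt3-2 (67.6% and 66.8% higher against 50.6% and 51.5%). Upper-quartile factors shifted the medians by 0.15 and 0.19.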

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

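Of the tests in this part, those of scaling and of exchanged genotype labels were chosen only after the result was seen.

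The genotype difference itself differed between shoots and roots by the interaction test, with a more positive effect in shoots for 5249 genes and in roots for 5293. Of the lists, camera called 10 at the preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05, and 19 by fry). Among these 10 the median interaction was log2 -4.23 for heat shock genes (adjusted p = 0.0595 with an estimated correlation), -3.43 for jasmonate, -1.84 for the cell cycle, -1.13 for salicylic acid, -0.99 for iron uptake and -0.78 for oxidative stress. It was 1.48 for iron storage, 1.01 for nitrate, 0.61 for the clock and 0.35 for glucosinolates. Single genes differed in the same test: AT5G52390 (-5.45), AT1G54050 (-5.23), AT1G55210 (-3.61), KELCH (-3.02), MYB10 (-2.49), BGLU42 (-1.95) and ZIF1 (-1.83) toward roots, and WRKY71 (3.00), VTL2 (2.92), FER4 (2.197), FER3 (1.95) and AHA2 (1.08) toward shoots. Of the 116 genes named for shoots or roots, 91 passed it, and of all 21887 genes 48.2% did. Apart from OPT3, the 116 were named by the size or p of their difference in the same libraries. That choice favours a high share, so the share is no separate evidence that the tissues differ.

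Genes called in both tissues moved more often in opposite directions than chance gives, but at 2-fold or more those higher in both also lay above chance (87 against 27.4), and 3 technical explanations were weighed. Run suffixes as the cause were predicted to bring the correlation of fold changes across genes above 0 when both genotypes share suffixes. The Spearman correlation there was -0.258. However, no wild type library has the full suffix set of the opt3-2 libraries, and the meaning of the suffixes is not stated. A batch tied to whole libraries would follow genotype and remain in that value, so this test cannot decide on such a batch. A scaling offset would enrich 1 of the opposite combinations, and the rarer of them stood at 1.66 times its chance number. Exchanged genotype labels in a tissue would turn OPT3 around, and the smaller log2 ratio of the lowest wild type to the highest opt3-2 library was 2.09. The tables argue against a scaling offset and exchanged labels, while a batch tied to whole libraries stays open. By the interaction test the difference between the labelled genotypes differed by tissue. Such a batch could enter that test too, because the wild type suffixes are split unevenly between shoots and roots. Whether a batch or leaf and root biology underlies the difference was not tested.

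Regrouping the libraries addressed whether chance can give as many genes. For the interaction, 1 of 100 regroupings, the real one, gave 10542 genes. Regroupings that mix the genotypes within a tissue remove the genotype difference itself and add it to the spread. They show that random genotype labels do not give as many genes. They cannot decide whether chance gives the difference between tissues. The highest other had 6863, from the regrouping in which the genotypes of 1 tissue were exchanged as a whole, which points to the genotype structure of the samples. The other comparisons allow 10 splits each, too few for a share under 0.05. The real split called 9617 genes in shoots (highest other 1), 8530 in roots (0), 17080 between wild type tissues (0) and 18513 between opt3-2 tissues (0), all by edgeR.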

How the results depend on the processing

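All alternatives were chosen before the data were examined. No named gene or list called with the main settings changed direction in an alternative run. For camera with an estimated correlation the direction was taken from the main settings, so no change could show there. Genes and lists called only in an alternative were not compared for direction. Of 146 named genes in their comparisons, 133 stayed on the same side of the threshold in every alternative. Among gene and alternative combinations 26 lost the call and 4 gained it, against 2950 on the same side; for lists these were 114, 101 and 2863. For the counts of genes and lists, 406 values lay within 1.5 times the reported count and 46 did not. Values that changed by more are given by setting. Their cause was not tested, except that stricter thresholds call less by construction. Settings with fewer runs or fewer libraries hold less data but need not call less.

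With a change of 2-fold or more required, the counts higher and lower were 521 and 1193 in shoots, 1151 and 576 in roots, 1264 and 2354 for the interaction, 5071 and 4648 between wild type tissues, and 6245 and 5031 between opt3-2 tissues. The overlaps were 87 higher in both, 18 lower in both, 41 higher in shoots and lower in roots, and 187 the other way. At an adjusted p under 0.01, 3052 genes were higher in shoots, and 2347 were higher and 2975 lower in roots, with overlaps of 293, 153, 866 and 659 in the same order. With run suffixes 2 and 3 only, roots had 1684 higher and 2119 lower and the interaction 3298 and 3409, with overlaps of 236, 122, 641 and 506. This setting leaves 1 wild type root library, which is assumed to vary like the other groups. With a term for suffixes 5 to 7, 288 genes were lower in both tissues. With technical replicate 1, 2 or 3 alone, 227, 251 and 253 genes were lower in both tissues and 1048, 1040 and 1039 higher in shoots and lower in roots, and with replicate 2 alone 389 were higher in both. limma-voom called 10 lists in shoots. With an estimated correlation, camera called 2 lists in shoots, 3 in roots and 0 for the interaction and each tissue comparison (6, 9 and 8 at an unadjusted p under 0.05), and fry called 17 lists in roots, 19 for the interaction and 27 between wild type tissues.

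Leaving out each replicate in turn gave 3528 to 4751 higher and 4085 to 5017 lower in shoots, 2823 to 3537 and 3745 to 4164 in roots, and 4684 to 5312 and 4723 to 5358 for the interaction. The replicate numbers do not pair the libraries: correlations between same-numbered libraries ran from -0.306 to 0.119, and between differently numbered ones from -0.378 to 0.389. With the number as a block, the counts were 4157 and 4537 in shoots, 3391 and 4149 in roots, 4853 and 4876 for the interaction, 8459 and 8249 between wild type tissues, and 9383 and 8814 between opt3-2 tissues. Depth limits genes near the floor of 3 counts.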

Other observations

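Of the tests in this part, all but that of run suffixes on the mitochondrial loci were chosen only after the result was seen, and the annotation terms were likewise tested after the values were seen.

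In opt3-2 shoots, genes for cytosolic ribosomes fell almost as a block. Of 99 genes of the large cytosolic subunit 99 were lower (median log2 -0.83; camera adjusted p = 2.53e-65, and adjusted p = 0.183 with an estimated correlation), and of 82 of the small subunit 79 were lower and 0 higher (median -0.75; adjusted p = 5.25e-46, and adjusted p = 0.183 with an estimated correlation). Genes of ribosome biogenesis were lower in 80 and higher in 4 of 98 cases (adjusted p = 0.183 with an estimated correlation), those of the endoplasmic reticulum lower in 120 and higher in 16 of 256 (adjusted p = 0.259 with an estimated correlation), and those of respiratory complex I lower in 22 and higher in 0 of 25 (adjusted p = 0.446 with an estimated correlation). Genes of the thylakoid membrane were higher in 110 and lower in 16 of 204 cases (median 0.28; adjusted p = 0.371 with an estimated correlation). The annotation term for the response to cadmium had 124 lower and 40 higher of 250 genes in shoots (adjusted p = 0.349 with an estimated correlation), and 96 higher and 22 lower in roots (adjusted p = 0.986 with an estimated correlation).

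In opt3-2 roots, proteasome genes were higher in 31 and lower in 0 of 45 cases (adjusted p = 0.00223, and 0.986 with an estimated correlation), and genes of toxin catabolism in 9 and 0 of 16 (adjusted p = 0.00223, and 0.929 with an estimated correlation). Of 231 terms of 15 to 500 genes, camera called 18 higher and 53 lower in shoots and 19 higher and 1 lower in roots. With an estimated correlation camera called 0 terms in each tissue, with 36 and 10 at an unadjusted p under 0.05.

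A pair of abundant mitochondrial loci was higher in opt3-2 roots: ATMG01390 went from 127 ± 11.4 to 460.4 ± 61.3 CPM (log2 1.86 ± 0.15) and ATMG00020 from 88.2 ± 2.49 to 257 ± 33.1 CPM (1.54 ± 0.19). The pair was picked for the highest means among mitochondrial loci in opt3-2 roots, the group where it is higher, which favours loci that rose. More mitochondrial RNA of every kind would raise the other 45 loci alike, and their upper quartile was 0.777 with a median of 0.35 (13 higher and 0 lower by edgeR). Weaker poly(A) selection would raise the long nuclear ribosomal RNA genes as much. AT2G01010 (0.61, adjusted p = 0.0262) and AT3G41768 (0.57, adjusted p = 0.0367) did rise by edgeR, and AT2G01020 (-0.53) and AT3G41979 (-0.55), the short ones, fell. The long ones rose less than the mitochondrial loci by 1.11 (SE 0.26). That SE treats the mitochondrial and nuclear loci as independent, although both were measured in the same root libraries. With shared run suffixes the mean of both mitochondrial loci was 1.74. That value cannot decide on a batch tied to whole libraries, because no wild type library has the full suffix set of opt3-2. The tables argue against a general rise or weaker selection as the whole cause, though each may account for part. Reads shared with nuclear copies of mitochondrial sequence may still contribute, which was not tested, and no biological explanation was tested.

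In wild type shoot replicate 2 the jasmonate genes lay below the other wild type shoot replicates, by a median log2 of -1.02 against replicate 1 and -1.03 against replicate 3. If RNA of opt3-2 shoots were mixed into that library, the 11 called jasmonate genes would need a share of 72.0%, while the genes most raised in opt3-2 shoots gave 5.18%, a ratio of 0.0720. The latter are the 5 genes named for the largest rises in shoots, a choice that favours genes low in every wild type shoot library. Their share may thus be too low for wild type shoot replicate 2. That library also lay nearer opt3-2 shoots on the second principal component (-25.0, against -52.3 and -47.9), a shift in a measure over all genes that goes with mixing, so the ratio argues against mixing only as the whole cause and a small share may be present. Run suffixes would leave it level with replicate 1, which has the same suffixes, and the value of -1.02 argues against that. No biological explanation was tested.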
